A study of Homo sapiens with 6 samples.

How the data were processed

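RNA was measured on Illumina bead arrays in 6 samples of UWB1.289 cells, 3 transfected with a scrambled siRNA and 3 with an siRNA against HBO1. Per the labels' protocols, total RNA was purified with a silica-column kit 48 hours after transfection in multiwell plates, and biotinylated cRNA was made with an amplification kit for Illumina arrays. GenomeStudio and lumi are named in the submitters' processing notes, with no version or setting. The siRNA sequences and the slide of each array are not given in the sources used here, so silencing of transcripts other than KAT7 by the siRNA was not examined and is not separated from loss of HBO1.

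The deposited table of probe intensity holds each probe's mean bead signal per array, and per the file headers these are average signals. The array medians in that table differ and its lowest values lie between 131.7 and 165.6, so it was taken as neither normalised nor background-subtracted. The same table gives a detection p-value for each probe and array, per the file headers, whose steps imply 770 negative control probes. A second table holds the authors' processed values, which were taken from the values to be log2 intensity. All 6 columns share a median of 6.31, so they were taken as normalised. The shared median does not show which normalisation was used or whether background was corrected. Each column of the authors' table tracked its own array, with a correlation of deviations of at least 0.9 against at most 0.28 for any other array. It served as an alternative.

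Intensities were background-corrected and quantile-normalised with neqc in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with negative controls inferred from the detection p-values and an offset of 16. A probe was tested when its detection p was under 0.05 on at least 3 of 6 arrays, which kept 21333 of 47316 probes. Depth has no counterpart on arrays, and precision was limited by the number of arrays. Signals near background are compressed by the offset, so folds of dim probes depend on it.

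Gene names came from the platform annotation supplied with the series: 30109 probes carried 1 symbol, 8 carried several, and 17207 had no single symbol and were left unnamed, including those 8. Symbols of 30070 probes were updated through their Entrez identifiers with the RefSeq gene table of assembly GRCh38.p14. No genome build was named for the probes, so no coordinates are given. Of the tested probes, 16248 had a gene name, for 12227 genes, and 5085 did not. A gene was represented by its probe with the highest mean intensity over all 6 arrays.

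Groups were compared with lmFit and eBayes in limma, on 2 group means with no covariate, as HBO1 siRNA minus control, and p-values were adjusted by Benjamini-Hochberg over all tested probes. The standard errors given are limma's moderated ones. A gene was called at an adjusted p under 0.05. Where a probe was undetected on all arrays of one group, the fold is a bound against the lowest detected signal of those arrays. Single values were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 arrays per group.

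Before the data were examined, 42 gene lists were written: 36 of pathways, 5 of cell types and 1 of reference genes. The 39 lists of pathways and cell types with at least 5 measured members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 39), beside camera with an estimated correlation, camera on ranks, and fry, which asks only whether a list moves on balance one way. The genes named were fixed by a rule at the same time: KAT7 and its complex subunits, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and per list up to 4 called members with the largest change, or 2 members given as values where 0 were called. Genes outside this rule are marked as chosen after their values were seen. The main test, the alternatives and the test designs were also fixed then. The alternatives were the authors' processed values, no background correction, median scaling, an offset of 50, no detection filter, a detection p under 0.01 on all 6 arrays, a trended and robust prior, array weights, an unmoderated fit, the replicate number as a block, adjusted p thresholds of 0.01 and 0.10, a gene as the mean of its probes or as its probe with the smallest p, and leaving out each array.

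The fit was tested on 10 simulated sets of 21333 probes drawn from the means and spreads of these arrays for HBO1 siRNA against control, each with 200 changed probes. It recovered 33.3% of changes of 1.5-fold, 89.4% of 2-fold and 98.9% of 3-fold, and 5.63% of its calls were unchanged probes. In further sets the interferon list was shifted by 0.2 on the log2 scale and genes varied independently. Camera called that list in 10 of 10 sets with the preset correlation and in 5 of 10 with an estimated correlation. It called 0 of 380 unshifted lists with the preset correlation. Because the simulated genes did not vary together, this does not show how often camera calls unshifted lists of genes that do. No array held the values of another, with 0 identical pairs among the 6.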

Results

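Transcript levels were measured in UWB1.289 cells, a human ovarian carcinoma cell line that lacks functional BRCA1, 48 hours after transfection with small interfering RNA (siRNA) against HBO1 or with a scrambled control siRNA. HBO1, encoded by KAT7 and formerly called MYST2, is a histone acetyltransferase that works in complexes with scaffold proteins of the BRPF and JADE families and has been linked to the licensing of replication origins. The data were 6 Illumina bead arrays, 3 from control siRNA cells and 3 from HBO1 siRNA cells, and the labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Between 20546 and 21507 of the 47316 probes were detected per array. The question put by the series is what loss of HBO1 does to gene expression in this line.

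The siRNA target was lower in HBO1 siRNA cells. The single KAT7 probe on the array (ILMN_1798187) fell from a normalised log2 intensity of 7.82 ± 0.23 (SD, n = 3) in control cells to 5.95 ± 0.35 (SD, n = 3), which left 27.3% of the control signal. The log2 fold change was -1.87, with a 95% confidence interval of -2.34 to -1.41 and a limma adjusted p = 0.0187. The control arrays read 7.98, 7.93 and 7.56, and the HBO1 siRNA arrays read 5.59, 6.29 and 5.98. The groups did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. KAT7 was detected on 3 of 3 control arrays and on 2 of 3 HBO1 siRNA arrays, so the residual signal lay close to background. The size depended on how background was removed, and without background correction the log2 fold change was -0.74. Its adjusted p rose above 0.05 on leaving out control replicate 2 (0.0968), control replicate 3 (0.0855), HBO1 siRNA replicate 1 (0.0595) or HBO1 siRNA replicate 2 (0.0605), with log2 fold changes between -2.04 and -1.69.

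**Figure D1:**
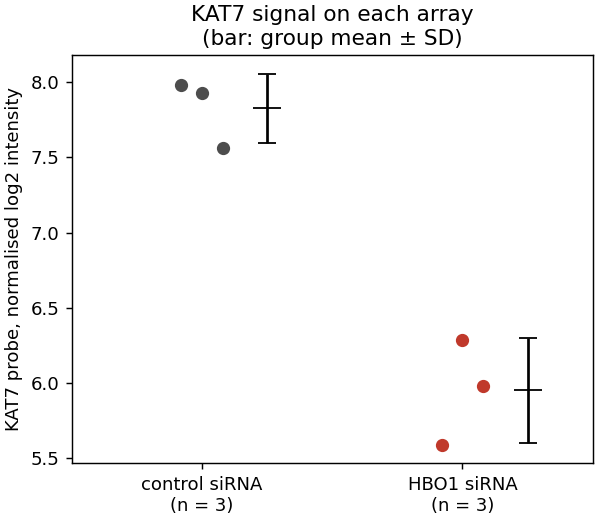
Normalised log2 intensity of the KAT7 probe (vertical axis) on each of the 3 control siRNA arrays and 3 HBO1 siRNA arrays (points), with each group's mean and SD (bars). The control arrays lie between 7.56 and 7.98 and the HBO1 siRNA arrays between 5.59 and 6.29.

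Many other transcripts differed between HBO1 siRNA and control siRNA cells. Among named genes, each taken by its brightest probe, the largest rises belonged to TCIM, a positive regulator of Wnt/β-catenin signalling, at 6.59-fold, and to DACT1, a Dishevelled-binding modulator of Wnt signalling, at 4.01-fold. PROC, the gene of the anticoagulant zymogen protein C, rose 3.44-fold, RASGRP1, an exchange factor that activates Ras, 3.02-fold, TSPAN8, a tetraspanin, 2.96-fold, and CCNG2, an atypical cyclin associated with cell cycle arrest, 2.92-fold. The other 2 CCNG2 probes were at 1.08 and 0.84 on the log2 scale and were not called (adjusted p = 0.056 for both). The log2 fold changes of these 6 genes were 2.72 (SE 0.29), 2.00 (SE 0.20), 1.78 (SE 0.26), 1.60 (SE 0.20), 1.57 (SE 0.25) and 1.54 (SE 0.26), with adjusted p from 0.0187 to 0.035. TCIM and DACT1 were each detected on only 1 of 3 control arrays, so their folds rest on a control level near background, and without background correction their log2 fold changes were 1.14 and 0.71. The next largest rises were those of KCNK12, a two-pore-domain potassium channel (1.49), TSHZ2, a zinc finger transcription factor (1.49), FAM107A, an actin-associated protein (1.48), RCAN2, a calcineurin regulator (1.43), GBP5, an interferon-inducible guanylate-binding protein (1.42), and PLA2G10, a secreted phospholipase (1.39), all as log2 fold changes. Without background correction, the rises of PROC, RASGRP1, TSPAN8, CCNG2, TSHZ2, RCAN2 and GBP5 were also smaller by over 1.5 times, with log2 fold changes from 0.48 for GBP5 to 1.00 for CCNG2.

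Among named genes, each taken by its brightest probe, the largest falls after KAT7 were those of RABL2B and RABL2A, Rab-like GTPases of the ciliary pathway, by 1.48 (SE 0.12) and 1.48 (SE 0.15) on the log2 scale. RABL2A and RABL2B are near-identical copies, so their probes cannot be assigned to one of them with certainty, and a second RABL2A probe (ILMN_1666624) was at 0.05 (adjusted p = 0.869), so that the mean over the RABL2A probes gave -0.90. SAR1A, the GTPase that starts COPII vesicle budding at the endoplasmic reticulum, fell by 1.47 (SE 0.11), which is 2.76-fold. CHORDC1, an HSP90 co-chaperone, fell by 1.40 (SE 0.11) and MEIOB, a meiotic recombination factor, by 1.33 (SE 0.15). SNAR-A1, a small NF90-associated RNA from a multicopy family whose members one probe cannot separate, fell by 1.30 (SE 0.14). Smaller falls were those of TMEM184A (-1.26), PDE1C, a calmodulin-dependent phosphodiesterase (-1.24), AFAP1L1, an actin filament-associated protein (-1.22), NEIL2, a base excision repair glycosylase (-1.18), and EOGT, an O-GlcNAc transferase of the endoplasmic reticulum (-1.16). Without background correction the falls of RABL2A (-0.65), MEIOB, TMEM184A, PDE1C, AFAP1L1, NEIL2 and EOGT were smaller by over 1.5 times, from -0.76 for AFAP1L1 to -0.50 for NEIL2. With background correction the adjusted p values of the falls lay between 0.0145 and 0.0216.

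**Figure D2:**
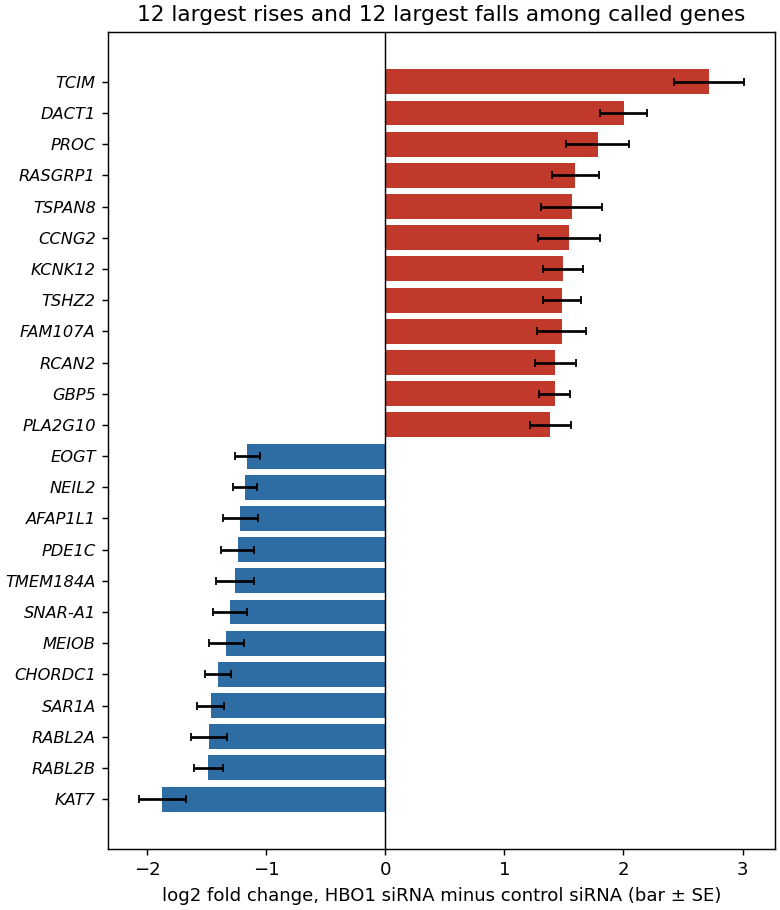
Log2 fold change of HBO1 siRNA against control siRNA (horizontal axis, bars, with SE as whiskers, n = 3 per group) for the 12 called genes that rose most and the 12 that fell most. TCIM reaches 2.72 and KAT7 -1.87.

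In limma's moderated test, 582 of 21333 probes passed a Benjamini-Hochberg adjusted p of 0.05, 314 of them higher and 268 lower. Taking the brightest probe of each gene, 390 of 12227 genes changed, with 234 higher and 156 lower, so 60.0% of the changed genes rose. Of these, 306 changed by at least 1.5-fold (185 up, 121 down) and 78 by at least 2-fold. Of the 101 changed genes with 2 or more tested probes, 96 had all probes moving in one direction, and 0 genes had probes called in opposite directions. Some named genes were called on 1 of several probes: a second probe was not called and moved less for RABL2B (-0.98), HIF1A (0.12), DDR1 (0.30), INSIG1 (0.30), JUP (0.38), SNAI2 (-0.39) and NOP56 (-0.29), and with the mean of a gene's probes MYL9, PARVB, CD47, HK2 and DDR1 lost their call. Another uncalled probe moved more than the called one for HIF1A (0.57, adjusted p = 0.0577) and NOP56 (-0.55, adjusted p = 0.0607). Another uncalled JUP probe was at 0.54 (adjusted p = 0.0518). At an unadjusted p of 0.05, 4570 probes passed, and for 27.1% of tested probes the groups did not overlap, where 10% is the share that chance gives. The balance of rises and falls depended on the scaling, since median scaling in place of quantile normalisation gave 42.9% rises (169 up, 225 down). It also ended the calls of TAGLN, MYL9, CDH1, CD47, IFIT1, DDIT4, HIF1A, H2BC5, NEU1 and ABCC3 and of 3 cholesterol genes. The number of genes rested on all 6 arrays: it was 63 without control replicate 1, 0 without control replicate 2, 0 without control replicate 3, 3 without HBO1 siRNA replicate 1, 1 without HBO1 siRNA replicate 2 and 180 without HBO1 siRNA replicate 3.

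The other subunits of the HBO1 complexes changed little. Of 9 measured subunits, ING4, a histone H3K4me3 reader of the JADE complexes, rose by 0.65 (SE 0.11, adjusted p = 0.0371), KAT7 fell, and 7 did not pass the test (the same 2 genes passed when adjusted over the list alone). The log2 fold changes of the others were -0.42 for ING5 (SE 0.22, detected on 1 of 3 HBO1 siRNA arrays), -0.19 for MEAF6 (SE 0.13), -0.06 for BRPF1 (SE 0.08), 0.26 for BRPF3 (SE 0.11), -0.18 for JADE1 (SE 0.12), -0.25 for JADE2 (SE 0.10) and 0.02 for JADE3 (SE 0.11), and the sign for JADE3 flipped with median scaling and without HBO1 siRNA replicate 3. Over the alternatives ING5 ranged from -0.64 to -0.13, MEAF6 from -0.29 to -0.10, BRPF1 from -0.21 to -0.04, BRPF3 from 0.17 to 0.33 and JADE1 from -0.23 to -0.002, where its brightest probe changed. Among 13 other lysine acetyltransferases, KAT2B, the acetyltransferase PCAF, fell by 0.82 (SE 0.10, adjusted p = 0.0209) and 12 did not pass. Adjusted over the list alone, 1 acetyltransferase rose and 1 fell. Without background correction ING4 was at 0.42. The acetyltransferase list's median was 0.01, its mean was -0.08 and its test pointed down (camera adjusted p = 0.48).

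Genes of replication licensing and origin firing, the process HBO1 is best known for, were slightly lower as a group. Of 27 measured members, 25 had a negative log2 fold change, with a list median of -0.13 and a camera adjusted p = 0.00604, and the adjusted p was 0.272 with an estimated correlation. In limma's test 0 members rose and 0 fell, also when adjusted over the list alone, and at an unadjusted p of 0.05 there were 6 lower and 0 higher. The largest values were -0.43 for MCM2, a subunit of the replicative helicase (SE 0.09, adjusted p = 0.055), and -0.37 for CDC7, the kinase that fires origins (SE 0.10). Of 20 alternative settings, MCM2 passed under 9 and stayed uncalled under 11, and CDC7 passed under 2 and stayed uncalled under 18. In the S-phase and DNA synthesis list, 0 of 33 members passed, over all genes or when adjusted over the list alone, with 3 lower and 1 higher at an unadjusted p of 0.05, a median of -0.08 and values of 0.39 for E2F1 (0.21 without background correction) and -0.32 for POLE2 (camera adjusted p = 0.104). The DNA repair and Fanconi anaemia list had 0 of 27 members past the threshold by either adjustment, 5 lower and 2 higher unadjusted, a median of -0.12 and values of -0.47 for FANCB (-0.26 without background correction) and -0.45 for MRE11 (camera adjusted p = 0.0981). The G2 and mitosis list had a median of 0.01, with 0 of 37 members called by either adjustment, 2 higher and 2 lower unadjusted, and 0.46 for KIF2C and -0.35 for NUF2 (camera adjusted p = 0.95).

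Individual regulators of the cell cycle and of cell death did change. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose 2.19-fold (1.13, SE 0.11, adjusted p = 0.0187), and TP53INP1, a p53-induced nuclear and autophagy protein, rose 2.23-fold (1.15, SE 0.15; 1.78 with adjusted p = 0.0187 on a second probe, ILMN_2214197), while FAS, a death receptor, fell by 0.72 (SE 0.13). Without background correction TP53INP1 was at 0.77 and FAS at -0.25. CDKN1A, TP53INP1 and FAS were the 3 of 20 p53 target genes that passed; adjusted over the list alone, 3 rose and 2 fell. The p53 list as a whole had a median of -0.01, a mean of 0.03 and a downward test (camera adjusted p = 0.873). Of 23 apoptosis regulators, BMF, a BH3-only protein that opposes BCL2, rose and 22 did not pass; adjusted over the list alone, 3 rose and 2 fell (camera adjusted p = 0.48). BMF was undetected on all control arrays, so its rise is given as at least 1.51-fold (adjusted p = 0.0284). Without background correction its log2 fold change was 0.27.

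Interferon response genes were higher as a group. Of 42 measured members, 41 had a positive log2 fold change, 6 rose and 0 fell over all genes tested, and 18 rose and 0 fell when adjusted over the list alone. OAS2, a double-stranded RNA sensor, rose by 1.03 (SE 0.11), GBP1, a guanylate-binding protein, by 0.96 (SE 0.11), IFIT1, an RNA-binding antiviral protein, by 0.87 (SE 0.16), and CXCL10, an interferon-induced chemokine, by 0.76 (SE 0.15). Without background correction OAS2 was at 0.44, IFIT1 at 0.42 and CXCL10 at 0.28. The list median was 0.31 (camera adjusted p = 1.31e-08; adjusted p = 0.221 with an estimated correlation). Among 30 NF-κB targets and inflammatory cytokines, 0 passed by either adjustment in limma's test, with 6 higher and 3 lower at an unadjusted p of 0.05, and the values were 0.82 for CCL2 (0.51 without background correction) and -0.74 for IL1A (-0.45 without HBO1 siRNA replicate 1) (camera adjusted p = 0.48).

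Probe signals of replication-dependent histone genes were also higher. Which forms of the histone transcripts were amplified for the arrays was not examined. Of 25 measured genes, 3 rose and 0 fell, and 7 rose when adjusted over the list alone. H3C4 rose by 0.88 (SE 0.14), H2BC5 by 0.79 (SE 0.13) and H2AC6 by 0.61 (SE 0.09). Without background correction H3C4 was at 0.26 and H2AC6 at 0.41. The list median was 0.32 (camera adjusted p = 1.6e-05; adjusted p = 0.401 with an estimated correlation). Histone genes are near-identical copies of each other, and H3C4 was detected on only 1 of 3 control arrays, so the assignment to single histone genes is uncertain.

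Ribosome biogenesis and MYC target genes were lower. Of 36 measured members, 34 had a negative log2 fold change, 4 fell and 0 rose over all genes, and 13 fell and 0 rose when adjusted over the list alone. RRP9, a U3 snoRNP protein of 18S rRNA processing, fell by 0.84 (SE 0.09), MYBBP1A, a nucleolar regulator of rRNA transcription, by 0.54 (SE 0.10), NOB1, the nuclease that makes the 3′ end of 18S rRNA, by 0.53 (SE 0.10), and NOP56, a core box C/D snoRNP protein, by 0.50 (SE 0.09). Without background correction RRP9 was at -0.53 and MYBBP1A at -0.31. The list median was -0.26 (camera adjusted p = 2.13e-08; adjusted p = 0.303 with an estimated correlation). Cytosolic ribosomal protein genes showed a median of -0.01, with 0 of 67 called by either adjustment, 2 lower and 1 higher unadjusted, and values of -0.36 for RPL37 (-0.18 without HBO1 siRNA replicate 2) and -0.31 for RPL29, in a list with camera adjusted p = 0.409. A second RPL29 probe (ILMN_1737517) was called at -0.55 (adjusted p = 0.045). Oxidative phosphorylation genes had a median of -0.004, with 0 of 56 called by either adjustment, 3 lower and 0 higher unadjusted, and values of -0.31 for UQCR11 (-0.19 without background correction) and -0.27 for NDUFV2 (camera adjusted p = 0.671).

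Among metabolic lists, cholesterol synthesis and lysosome genes were higher. HMGCS1, which makes the HMG-CoA of the mevalonate pathway, rose by 0.58 (SE 0.11), INSIG1, a sterol-sensing retention factor, by 0.52 (SE 0.10) and LPIN1, a phosphatidate phosphatase, by 0.49 (SE 0.09), while LSS, lanosterol synthase, fell by 0.63 (SE 0.09). With median scaling HMGCS1, INSIG1 and LPIN1 lost their call and LSS kept it. With quantile normalisation these were the 3 rises and the 1 fall among 28 cholesterol synthesis genes; 9 rose and 1 fell when adjusted over the list alone, and the list median was 0.16 (camera adjusted p = 0.00132; adjusted p = 0.362 with an estimated correlation). Of 39 autophagy and lysosome genes, ULK1, the kinase that starts autophagy, rose by 0.79 (SE 0.12) and NEU1, lysosomal sialidase, by 0.49 (SE 0.08), 0 fell, and 4 rose when adjusted over the list alone. The median of that list was 0.09 (camera adjusted p = 0.00926; adjusted p = 0.221 with an estimated correlation).

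**Figure D3:**
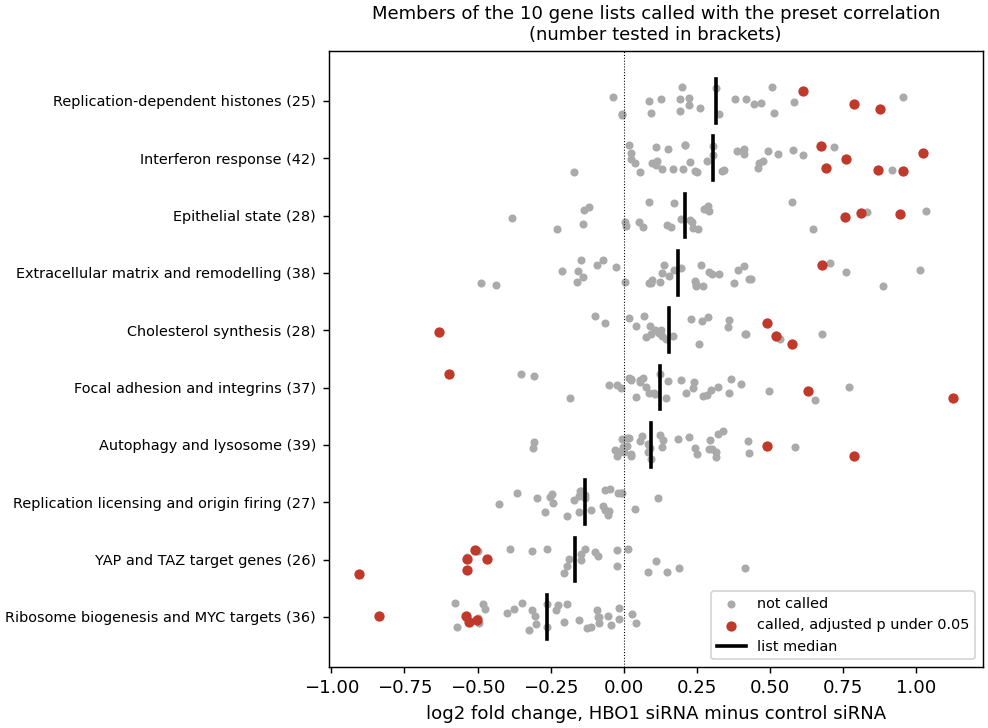
Log2 fold change (horizontal axis) of each measured member (points) of the 10 lists called with camera's preset correlation, with called members in red and list medians as black bars. Medians run from -0.26 for ribosome biogenesis to 0.32 for replication-dependent histones, and none of the 10 lists passed with an estimated correlation, where adjusted p was 0.221 or higher.

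Adhesion genes moved in several directions. YAP1, the transcriptional coactivator of the Hippo pathway, fell by 0.91 (SE 0.13, adjusted p = 0.0255). Of 26 genes in the YAP and TAZ list, which counts YAP1 itself, 5 fell and 0 rose, with 7 falls and 1 rise when adjusted over the list alone. Besides YAP1, the falls included DLC1 (-0.54, SE 0.10), FJX1 (-0.54, SE 0.09) and CRIM1 (-0.51, SE 0.09). Without background correction DLC1 was at -0.35. The list median was -0.17 (camera adjusted p = 0.00132, or adjusted p = 0.221 with an estimated correlation). Of 37 focal adhesion and integrin genes, ITGB6, an epithelial integrin subunit, rose by 1.13 (SE 0.13), TES, a focal adhesion LIM protein, rose by 0.63 (SE 0.09) and PARVB, an integrin-linked kinase partner, fell by 0.60 (SE 0.12), and adjusted over the list alone 6 rose and 1 fell. The median was 0.13 (camera adjusted p = 0.00512; adjusted p = 0.221 with an estimated correlation). A second TES probe (ILMN_1746243) was at 0.24 (adjusted p = 0.283). Without background correction ITGB6 was at 0.54. MMP14, a membrane-bound collagenase, rose by 0.68 (SE 0.12; 0.26 without background correction), the 1 extracellular matrix gene of 38 to pass, and 2 rose when adjusted over the list alone. That list's median was 0.18 (camera adjusted p = 0.0232; adjusted p = 0.506 with an estimated correlation). Its call ended without control replicate 1, without HBO1 siRNA replicate 2 and without HBO1 siRNA replicate 3, where the adjusted p reached 0.122, as well as at detection p under 0.01 on all 6 arrays, at an adjusted p under 0.01 and in fry (0.0504).

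Epithelial genes were higher. CD24, a surface sialoglycoprotein, rose by 0.94 (SE 0.10), JUP, plakoglobin, by 0.81 (SE 0.10) and CDH1, E-cadherin, by 0.76 (SE 0.13), which were 3 of 28 measured epithelial genes, with 0 falls; 6 rose and 1 fell when adjusted over the list alone. The list median was 0.21 (camera adjusted p = 0.00604; adjusted p = 0.56 with an estimated correlation), and the adjusted p was 0.112 without HBO1 siRNA replicate 1 and 0.0942 in fry. Of 20 mesenchymal genes, SNAI2, the E-cadherin repressor SLUG, fell by 0.81 (SE 0.13; -0.51 without background correction) and 19 did not pass, with 0 rises and 2 falls when adjusted over the list alone. The mesenchymal median was 0.08, the mean 0.04 and the test pointed down (camera adjusted p = 0.95). Among 56 actin genes, TAGLN (0.55, SE 0.11) and MYL9 (0.52, SE 0.10), a contractile actin-binding protein and a myosin light chain, rose and 0 fell, with 3 rises when adjusted over the list alone (camera adjusted p = 0.0981). TAGLN and MYL9 were also the 2 rises among 22 SRF and MRTF targets, where LIMA1, an actin-bundling protein, fell by 0.62 (SE 0.11), and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.671). Of 32 caveolar and cortex genes MARCKSL1 (0.84) and CD47 (0.68) rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.104), and 0 of 15 nuclear lamina genes passed by either adjustment, with 2 higher and 0 lower unadjusted and values of 0.37 for SYNE2 (0.17 to 0.53 over the alternatives) and 0.32 for SUN2 (camera adjusted p = 0.564).

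Several signalling genes changed in lists that camera did not call. In the TGF-β and BMP list, ID2, an inhibitor of basic helix-loop-helix factors, rose 2.44-fold (1.28, SE 0.17), BMP2, a ligand, rose by 0.95 (SE 0.14), BMPR2, its receptor, rose by 0.74 (SE 0.09) and SMAD2, a signal transducer, fell by 0.65 (SE 0.13). Without background correction BMP2 was at 0.48 and SMAD2 at -0.24, where SMAD2 lost its call. In all, 4 of these 33 genes rose and 1 fell, and 8 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.247). FOSL1, an AP-1 subunit, fell by 1.12 (SE 0.22) and HBEGF, an EGF receptor ligand, by 0.93 (SE 0.16), the 2 of 28 immediate early genes to pass, with 1 rise and 4 falls when adjusted over the list alone (camera adjusted p = 0.401). MERTK (0.78, SE 0.10) and DDR1 (0.69, SE 0.10), 2 receptor tyrosine kinases, rose while HBEGF fell among 33 growth factor receptors and ligands, with 8 rises and 4 falls when adjusted over the list alone (camera adjusted p = 0.857). FZD7, a Wnt receptor, rose by 0.84 (SE 0.10) as 1 of 32 Wnt genes, by either adjustment (camera adjusted p = 0.496). A second FZD7 probe (ILMN_2108823) was at 0.02 (adjusted p = 0.931) and the mean of its probes was 0.43. TSC22D3, the glucocorticoid-induced leucine zipper, rose 2.03-fold (1.02, SE 0.13) as 1 of 13 genes of the steroid receptor list, with 2 rises when adjusted over the list alone (camera adjusted p = 0.518).

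Individual stress and metabolic regulators changed. BHLHE40, a circadian and hypoxia-responsive repressor, rose by 0.87 (SE 0.13), DDIT4, an inhibitor of mTORC1, by 0.69 (SE 0.12) and HIF1A, the hypoxia-inducible factor, by 0.51 (SE 0.08), while HK2, hexokinase 2, fell by 0.60 (SE 0.12), with -0.16 (adjusted p = 0.421) on a second HK2 probe (ILMN_2156172) and -0.38 for the mean of its probes; these were the changes among 35 glycolysis and hypoxia genes, with 5 rises and 2 falls when adjusted over the list alone (camera adjusted p = 0.387). DDIT4 was the 1 rise among 39 ATF4 targets by either adjustment (camera adjusted p = 0.749). DERL1, an endoplasmic reticulum degradation factor, fell by 0.67 (SE 0.12) as 1 of 29 unfolded protein response genes by either adjustment (camera adjusted p = 0.518). ABCC3, a transporter, rose by 0.47 (SE 0.09) as 1 of 30 NRF2 targets, with 2 rises and 1 fall when adjusted over the list alone (camera adjusted p = 0.857). TNRC6B, a GW182 protein of microRNA silencing, rose by 0.91 (SE 0.17) as 1 of 14 genes of RNA interference by either adjustment, in a list whose median was -0.07, mean 0.02 and test downward (camera adjusted p = 0.857). HOX genes gave 0 calls of 18 by either adjustment, with 2 higher and 1 lower unadjusted and values of 0.62 for HOXC13 (SE 0.34), which was 0.18 without HBO1 siRNA replicate 2, and 0.45 for PBX3 (camera adjusted p = 0.518).

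Markers of the line's own lineage were present and some rose. MUC16, the gene of the CA-125 antigen, rose 2.51-fold (1.33, SE 0.18, adjusted p = 0.0243), and with CD24 it made 2 rises and 0 falls among 13 measured markers of ovarian carcinoma and Müllerian epithelium, or 3 rises and 1 fall when adjusted over the list alone (camera adjusted p = 0.0981). Markers of other cell types gave 0 calls over all genes: leukocyte markers (8 measured of 22, median 0.10, with 0.79 for CD14 and 0.48 for ITGAM), fibroblast markers (6 of 15, median 0.10, with 0.66 for THY1, SE 0.39, and -0.42 for PDPN), endothelial markers (4 of 14, median 0.25, with 0.68 for PECAM1 and 0.44 for PLVAP, SE 0.38) and markers of other tissues (4 of 20, median -0.17, with -0.28 for CDX2 and -0.23 for LIN28B). At an unadjusted p of 0.05 in limma's test, 2 leukocyte markers, 1 fibroblast marker and 1 endothelial marker were higher and 1 fibroblast marker was lower, and 1 endothelial marker rose when adjusted over the list alone. Over the alternatives, values ranged from 0.28 to 0.97 for THY1, 0.10 to 0.79 for PLVAP, 0.25 to 0.80 for PECAM1, 0.42 to 0.99 for CD14, 0.16 to 0.58 for ITGAM, -0.43 to -0.08 for CDX2 and -0.42 to -0.06 for LIN28B. Camera adjusted p was 0.418 for leukocyte and 0.857 for fibroblast markers. Of 14 reference genes, 0 passed by either adjustment, with 1 higher and 1 lower unadjusted and values of -0.58 for PPIA and 0.32 for GUSB. Without background correction PPIA was at -0.25.

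The arrays separated by siRNA. The first principal component of the tested probes held 44.2% of the variance and placed the control arrays between -26.9 and -12.0 and the HBO1 siRNA arrays between 9.36 and 30.2. Pearson correlations between arrays across probes, which are not independent replicates, were 0.991 to 0.994 within groups and 0.984 to 0.990 between groups. HBO1 siRNA arrays had fewer detected probes, 20546 to 21175 against 21262 to 21507 in control arrays, and the two-sided exact permutation p of 0.1 was the smallest possible. Raw median intensities were 205.4 to 239.0 against 224.1 to 242.6 (two-sided exact permutation p = 0.4).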

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

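How many genes passed depended on the threshold, the variance model and the number of arrays. Under the authors' processed values, no background correction, an offset of 50, a detection p under 0.01 on all 6 arrays, a trended and robust prior, array weights and an adjusted p under 0.10, 979, 1811, 1020, 1136, 1886, 913 and 1665 probes passed (582 in the main analysis), and 682, 1307, 713, 808, 1348, 623 and 1104 genes (390). The mean of a gene's probes gave 726 genes. Without a detection filter 247 probes, 171 genes and 170 genes of at least 1.5-fold passed. The unmoderated fit gave 6, 3 and 1, and an adjusted p under 0.01 gave 2, 0 and 0. Genes of at least 1.5-fold (306) were 191 without background correction, 569 with the trended prior and 560 at an adjusted p under 0.10. Leaving out each array gave 1 to 268 probes, 0 to 180 genes, and 0 to 180 genes of at least 1.5-fold, with fewer samples as part of the construction. At an adjusted p under 0.01 and without control replicates 2 or 3 no share of rises could be computed.

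The share of rises (60.0%) reversed to 42.9% with median scaling, was 67.2% without a detection filter and 66.7% in the unmoderated fit, and ranged from 60.6% to 100% on leaving out arrays; the cause was not tested. KAT7 fell under every setting that tested it, with log2 fold changes from -2.04 to -0.74; it lost its call in the unmoderated fit (-1.87, adjusted p = 0.0996), at an adjusted p under 0.01 (-1.87, adjusted p = 0.0187), and in 4 of the fits leaving out an array (-2.04 to -1.69). The adjusted p of KAT7 ranged from 1.07e-04 to 0.0996 over its alternatives, and it was not tested with the stricter detection filter. JADE3, at 0.02, reversed to -0.050 with median scaling and to -0.083 without HBO1 siRNA replicate 3, within -0.083 to 0.079 on leaving out arrays. Of the 116 named genes other than KAT7, 113 stayed on their side of the threshold with the authors' processed values, 102 with median scaling, 81 without a detection filter, 81 with the replicate block, 36 in the unmoderated fit, and 35 to 78 on leaving out an array, where the brightest probe of TES, RPL29 and JADE1 changed in some fits. Named genes that were uncalled in the main analysis count among those that stayed. Without control replicate 2 or control replicate 3, 81 named genes lost their call, and 0 of the 390 called genes kept theirs. In the unmoderated fit 80 named genes lost their call, and 2 of the 390 kept theirs. All 10 called lists kept their direction, 0 passed with an estimated correlation and 19 lists passed in fry, which compares no list with other genes and did not call 2 of the 10, the epithelial (adjusted p = 0.0942) and extracellular matrix (0.0504) lists. Leaving out each array gave 9 to 10 lists. Whether equal replicate numbers mark pairs is not known here: the deviations of equal-numbered arrays correlated at 0.26, -0.02 and 0.22 and those of other pairs at 0.09 or less, both replicate 1 arrays lay together on the second principal component (20.8 and 18.3), and not every array correlated best with its own number; with the replicate number as a block, 282 probes, 202 genes and 202 genes of at least 1.5-fold passed, 70.8% of them rises, and 10 lists. A slide block was not run, because the slide of each array was not known here.

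There were 10 ways to split the 6 arrays into 3 and 3. The real split gave 582 probes, 390 genes and 306 genes of at least 1.5-fold, against at most 0 in the others. It gave 10 lists, and the others gave 0 to 8. In some of them these included the NF-κB, unfolded protein response, immediate early and NRF2 lists, which the real split did not call. Each other split mixes both siRNAs in each group, so it keeps part of the real difference. That part does not by itself account for the lists that the real split left uncalled. Camera with the preset correlation thus also called lists where 0 genes were called. The 10 splits are too few for a share under 0.05. Signal over background limits KAT7, ING5, TCIM, DACT1, GBP5, BMF, H3C4, PLVAP and CDX2, which were undetected on some arrays.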

Other observations

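The genes named in this part were chosen after their values were seen, and the test of the NF-κB list and the matched-list test of the neuronal genes were chosen only after their results were seen, the latter in place of a test on an intensity range that was set aside as void because normalisation fixes its outcome. The other tests were set out before their results. MACROH2A1, the histone variant macroH2A1, fell on all 3 of its tested probes, by 1.60 (SE 0.12), 1.17 (SE 0.10) and 0.73 (SE 0.09) on the log2 scale. The probes thus fell by unequal amounts, with adjusted p values of 0.0145, 0.0149 and 0.0216. SNAPC1, a subunit of the complex that starts small nuclear RNA transcription, fell by 1.92 (SE 0.19) on one probe and by 0.79 (SE 0.13) on its brighter one. Subunits of the epithelial sodium channel rose, SCNN1A by 1.18 (SE 0.21) and SCNN1G by 1.06 (SE 0.15). The probe ILMN_3274914, which has no gene name here, fell by 2.99 (SE 0.11, adjusted p = 4.07e-04), more than KAT7, and ILMN_3203874 was undetected on all HBO1 siRNA arrays and at least 3-fold lower; ILMN_1764709 rose by 2.03. In all, 77 of the 582 called probes had no gene name.

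As the starting point of a hypothesis, ribosome biogenesis genes were lower (median -0.26; camera adjusted p = 2.13e-08, or 0.303 with an estimated correlation), while CCNG2 (1.54, with 1.08 and 0.84 on uncalled probes), KLHL24 (1.39) and TP53INP1, genes known to be induced by FOXO transcription factors, were higher. The ribosome biogenesis median of -0.262 lay outside the -0.057 to 0.071 that held the middle 95% of 10000 random lists matched on intensity. These genes thus moved apart from others of like brightness. Normalisation holds such random lists near 0, so the comparison cannot exclude that processing contributed. If growth signalling were lower and FOXO factors more active, other FOXO targets should rise, so a list of 23 further FOXO targets and factors was written that left out the risen genes already seen. Of its 20 measured members, 19 had a positive log2 fold change and 4 rose (FBXO32 0.87, HBP1 0.64, BTG1 0.61 and FOXO3 0.48, with 0.21 on an uncalled FOXO3 probe), the median was 0.44 against -0.11 to 0.13 in matched lists, and the camera p was 2.88e-08, or p = 0.0081 with an estimated correlation. The list's mean was 0.42, against -0.24 in the most extreme other split of the arrays. Every other split mixes both siRNAs in each group, which makes its mean smaller by construction, so that comparison adds no support. Reduced growth signalling with active FOXO factors may be worth testing at the protein level, where these arrays say nothing.

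The interferon genes, with a median of 0.307, lay above the -0.079 to 0.098 of intensity-matched random lists, so they moved apart from other genes of like brightness. Quantile normalisation holds such random lists near 0, so the comparison cannot exclude that processing contributed. Control cells also received a duplex, the scrambled siRNA, so a response common to both duplexes would be present in both groups. A response that differs between the duplexes, whatever their targets, remains possible. NF-κB targets, which duplex sensing could raise as well, had a camera adjusted p = 0.48. Each siRNA marks one group, so a difference between the duplexes and the loss of HBO1 cannot be told apart here. The loss of HBO1 stays open as an untested biological explanation.

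Some genes best known from neurons rose, and since they were picked after their values were seen they are no test of a neuronal theme: MAP2 by 1.24 (SE 0.13; -0.075 on an uncalled probe), TUBB3 by 1.00 (SE 0.09), TUBB2B by 1.07 (SE 0.17), SYT1 by 0.94 (SE 0.11), SYT11 by 1.09 (SE 0.17) and VSNL1 by 1.31 (SE 0.22; 0.53 on an uncalled probe). The middle 95% of 10000 random lists matched on intensity had medians of -0.22 to 0.25, below the 1.08 of these 6 genes. Because the 6 were picked for having risen, that gap was fixed in advance and cannot decide whether a brightness-dependent shift contributed. Relief of repression by REST, the repressor of neuronal genes, might raise such genes, and a list of 41 other neuronal genes repressed by REST was tested. Of 19 measured members, 2 rose (CELSR3 0.80 and SNAP25 0.70) and 0 fell, 11 were higher and 8 lower by sign, the median was 0.05, inside the -0.12 to 0.15 of matched lists, and the unadjusted camera p was 0.0749. The list left out genes already seen to rise, so that result leaves the hypothesis open.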
